A study of Homo sapiens with 2 samples.

How the data were processed

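Total RNA from cultured HL-60 and THP1 cells was depleted of ribosomal RNA and sequenced on the SOLiD platform, per the labels' protocols. The authors deposited 1 table per line of RPKM values, reads scaled by gene length and mapped reads, with an Ensembl identifier for every gene and a symbol for 18031. The aligner, the genome build, the annotation release, the gene length used and the treatment of reads with several matches are not given in the sources used here. RPKM depends on what else was sequenced, since a class of abundant short RNAs lowers the value of every other gene.

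Depth was recovered from the values. In annotated genes of up to 200 nt, with an RPKM under 30, RPKM times length is a whole number of reads at the right depth. At 16310000 reads, 94.7% of 618 genes in the library labelled HL-60 came within 0.05 of a whole read, and at 18350000 reads 94.4% of 645 genes in the library labelled THP1. Lengths were merged exons of GENCODE 29 (GRCh38), matched by Ensembl identifier to 35081 genes. In protein-coding genes of up to 1500 nt with under 12 reads, only 51.3% of 193 and 46.3% of 188 came within 0.1 of a whole read, so read numbers of coding genes are approximate. Fold intervals are exact binomial and RPKM intervals exact Poisson, both at 95%; they cover counting error only. A floor of 3 reads corresponds to an RPKM of 0.18 and 0.16 in a gene of 1 kb. A listed 0 can be a failed estimate, so no fold is given against one; counts past the size rule and list medians include such genes.

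Genes with an RPKM of at least 1 in either library entered the comparison. The ratio was log2 of RPKM + 1, labelled HL-60 over labelled THP1, which understates the change of low genes. With 1 library per line, a 4-fold size rule replaced a test. The 31 gene lists, the size rule, the alternatives and the rule for named genes were fixed before the data were examined. That rule took the 12 largest ratios in each direction at an RPKM of at least 5, the 8 highest genes of each library, up to 4 members of each list with the largest ratios together with its highest member, and a fixed set of myeloid and leukaemia genes. Genes in the closing section that fall outside it, and SLC4A1, were named after their values were seen. Sex-specific genes were left out. Some genes and 1 of the lists are not reported here.

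Each list's median ratio was placed among 10000 random lists of the same size, drawn with replacement and matched on mean expression in 10 bins. Lists with fewer than 5 detected members got no percentile. Percentiles describe these libraries. Names follow GENCODE 29 by identifier. The list names DEFA3, HBB, PSMB9 and TLR9 matched a row by its deposited symbol whose identifier belongs to another gene; the row with the symbol HBB carries the identifier of HBD. How reads shared by near-identical copies were counted and whether strand was used are not given in the sources used here, so histone, HLA and globin genes, overlapping genes and antisense genes are uncertain singly.

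Alternatives were values divided by their sum, the same without the 50 highest rows, ratios centred on their median or on a mean trimmed by 30% at each end, pseudocounts of 0.1, 0.5 and 5, no filter, an RPKM of at least 5, at least 20 reads, summed rows of a symbol, an 8-fold threshold and unmatched random lists. In simulated data for the comparison of the libraries, with counting error only and 11205 genes, changes were planted in genes with a mean RPKM of at least 5. There the size rule recovered 100% of 100 genes changed 16-fold and 99% of 100 changed 6-fold. It called 0.027% of 11005 unchanged genes. Recovery among lower genes was not tested. The list method was tried on the observed ratios, with random lists of 20 genes that carry a symbol. Of 200 such lists raised by 1 log2 unit 200 lay above the range, and of 200 left as they were 6 lay outside it. Smaller lists were not tried. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.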

Results

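Steady-state transcriptomes were compared between HL-60, a promyelocytic acute myeloid leukaemia cell line that can be driven towards granulocytes, and THP1, a monocytic acute leukaemia line known to carry a fusion of KMT2A with MLLT3. Ribosomal RNA-depleted total RNA from cultured cells was sequenced on the SOLiD platform, with 1 library per line. The series names a further cell line, which was not analysed here. The tables gave RPKM values for Ensembl genes, 24343 of them without a symbol, and 11265 genes reached an RPKM of 1 in the library labelled HL-60 and 10158 in the library labelled THP1. The depth recovered from the values was 16310000 mapped reads for the library labelled HL-60 and 18350000 for the library labelled THP1. With 1 library per line there was no replicate check and no test, so differences describe these libraries, and intervals given with folds cover counting error only. MPO, MYC, HOXA9 and MEIS1, known to separate the lines, ran against the names of the libraries, and each direction below is therefore that of the library labelled with a name.

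The first question was which genes differed most between the lines. The library labelled THP1 had more MPO, the myeloperoxidase of primary granules (chromosome 17, 58269856 to 58280935, GRCh38), at an RPKM of 476 against 3.71, which was 128-fold (95% counting interval 112 to 148). PRG2, the eosinophil major basic protein, was 82.6-fold higher there (62.1 to 113), and TRIB1, a pseudokinase that regulates C/EBP proteins, 109-fold higher (69.0 to 175). In the opposite direction the library labelled HL-60 had more IL32, a cytokine gene, at 127 against 1.24, which was 103-fold (81.5 to 131), and more CD93, a receptor of early myeloid cells, at 78.9 against 1.31. PDK1, a kinase that restrains pyruvate dehydrogenase, stood at 131 against 5.02, or 26.1-fold (24.8 to 27.6).

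Of 12066 detected genes, 312 were at least 4-fold higher in the library labelled HL-60 and 272 at least 4-fold higher in the library labelled THP1 on the log2(RPKM + 1) scale. The median log2 ratio over the 9357 genes detected in both libraries was 0.37, a 1.29-fold shift towards the library labelled HL-60. Centred on that shift, the counts were 160 and 405, so that the share of calls higher in the library labelled HL-60 went from 53.4% to 28.3%. Among genes with a symbol, a restriction chosen after the data were seen, the counts were 216 and 76, a share of 74.0%, and centred 106 and 111, a share of 48.8%. Among genes without one they were 96 and 196, a share of 32.9%, and centred 54 and 294. Across genes, which are not independent replicates, Spearman's rho between the libraries was 0.80 and Pearson's r of log2(RPKM + 1) was 0.88. Relative values below are log2 ratios, labelled HL-60 over labelled THP1, minus that shift.

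**Figure D1:**
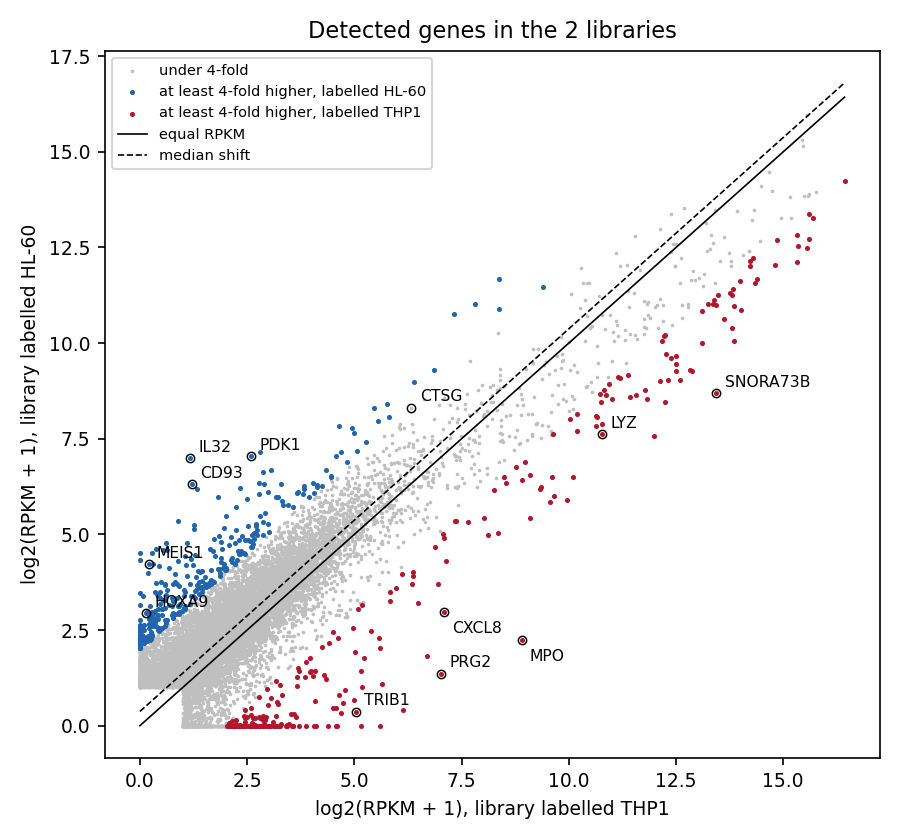
Each point is 1 of the 12066 detected genes, with log2(RPKM + 1) in the library labelled THP1 on the horizontal axis and in the library labelled HL-60 on the vertical axis; coloured points are at least 4-fold apart, the solid line marks equal RPKM and the dashed line the median shift of 0.37. MPO lies far to the right at 476 against 3.71, and IL32 and CD93 lie at the upper left.

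The 12 genes with the largest ratios on the HL-60 side included 4 neighbours in the natural killer gene complex of chromosome 12 (GRCh38), between CLECL1, which starts at 9715860, and CLEC2A, which ends at 9932381. CLEC2B stood at 71.6 against 1.5, CLECL1 at 39.7 against 0.86, CD69 at 23.4 against 0.29 and CLEC2A at 22.0 against 0.22. On the THP1 side PTPRCAP, which encodes a partner of the CD45 phosphatase, had an RPKM of 47.1 and was listed at 0 in the library labelled HL-60. Short RNA genes made up part of that side, among them SNORA73B at 11111 against 414, MIR181A1 at 49.0 against 1.12 (about 2 reads, 43.8-fold, interval 11.9 to 368), and MIR302A at 34.7 against a listed 0. HIST1H2BB and HIST1H3J on one side and HIST1H2BG on the other, all histone genes with near-identical copies, are uncertain at the level of the single gene.

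The second question was how myeloid differentiation genes differed. Azurophil granule genes went both ways: of 12 detected, 4 were at least 2-fold higher in the library labelled HL-60 relative to the shift and 4 in the library labelled THP1. PRTN3, a serine protease of these granules, was 5.79-fold higher in the library labelled THP1 (5.08 to 6.61), and BPI, which binds bacterial endotoxin, stood at 8.09 there against 0.19. RNASE3, the eosinophil cationic protein, and CTSG, cathepsin G, were higher in the library labelled HL-60, at 26.3 against 1.14 and at 317 against 79.6. ELANE, neutrophil elastase, at 40.4 and 36.7, and AZU1, at 33.2 and 36.0, differed by no more than counting error and change sides with the scaling. The list median of 0.01 lay at percentile 17.7 of matched random lists, and at 0.09, below the range, with no filter.

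Specific and gelatinase granule genes were lower in the library labelled HL-60, with all 5 detected members lower and a list percentile of 0.23, but 3 of the 5 were listed at 0 there, and without genes listed at 0 too few members were left for a percentile. CHI3L1, a chitinase-like protein, stood at 3.11 against 47.1, and CYBB, the catalytic subunit of the phagocyte oxidase, was 2.74-fold higher in the library labelled THP1 (2.55 to 2.94). HP, ARG1 and PGLYRP1 were listed at 0 in the library labelled HL-60 and at 5.84, 2.19 and 2.42 in the library labelled THP1. Myeloid and haematopoietic transcription factors also lay low, at percentile 0.17, with 13 of 33 members at least 2-fold lower relative to the shift and 1, ID2, higher; at an RPKM of at least 5 the list lay within the range, at 2.53. FOS stood at 3.94 against 46.4, CEBPE, a factor of late granulocyte maturation, at 5.77 against 19.4, and MYC at 73.0 against 167. SPI1, the master regulator PU.1, stood at 74.3 against 109, and GFI1 at 41.5 against 32.9, values that change sides with the scaling.

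Of 18 detected monocyte and macrophage markers, 5 were at least 2-fold higher in the library labelled THP1 relative to the shift and none in the library labelled HL-60; the list percentile was 6.14. S100A8 stood at 2.44 against 36.4, S100A9 at 16.8 against 66.6 and TYROBP, an adaptor of activating receptors, at 13.0 against 38.6. CD14, the endotoxin co-receptor, stood at 0.04 against 2.06, a ratio of 51.5 (10.97 to 2527) that rests on about 1 read in the library labelled HL-60. LYZ, lysozyme, stood at 196 against 1758. MNDA, the highest on average of the monocyte list, was 1.74-fold higher in the library labelled HL-60 (1.63 to 1.86), and CSF1R was low in both, at 0.17 and 0.18. Progenitor and early myeloid surface markers, at percentile 13.0, held both CD38, at 5.84 against 0.80, and FLT3, at 1.08 against 4.84.

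**Figure D2:**
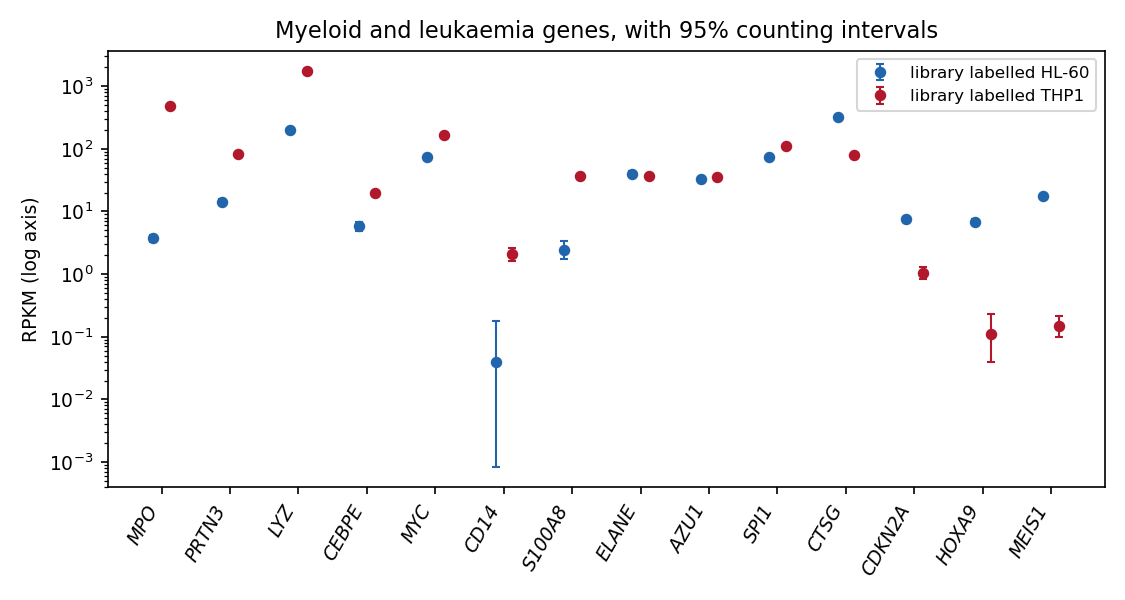
RPKM of myeloid and leukaemia genes on a log axis in the library labelled HL-60 and the library labelled THP1, with 95% Poisson counting intervals from approximate read numbers. MPO, PRTN3 and LYZ are higher in the library labelled THP1, HOXA9 and MEIS1 higher in the library labelled HL-60, and the intervals of ELANE overlap.

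The third question was how genes tied to KMT2A-rearranged leukaemia differed. The HOXA cluster and its partners stood higher in the library labelled HL-60, with all 8 detected members above the shift, 5 of them at least 4-fold higher, and a list median of 2.19 that exceeded every matched random list. MEIS1, a homeodomain partner of HOXA9 (chromosome 2, 66433452 to 66573869, GRCh38), stood at 17.7 against 0.15, which was 118-fold (82.8 to 176). HOXA9 (chromosome 7, 27162435 to 27175180) stood at 6.70 against 0.11 and HOXA10 at 7.67 against 0.17. Chromatin regulators and KMT2A partners as a list lay at percentile 50.03; within it BMI1, a Polycomb protein, was 14.0-fold higher in the library labelled HL-60 (12.4 to 15.8), TET2 stood at 1.56 against 5.68 and MLLT3 at 2.92 against 0.77. KMT2A itself stood at 6.82 and 4.71. Of cell cycle inhibitors, CDKN2A stood at 7.46 against 1.04 and RB1 at 16.8 against 4.43, and MTAP, the neighbour of CDKN2A, stood at 4.78 against 3.07.

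Erythroid genes were higher in the library labelled THP1, where 15 of 16 detected members stood at least 2-fold higher relative to the shift and the list median lay below every matched random list, also without the 8 members listed at 0 in the library labelled HL-60. AHSP, the chaperone of alpha globin, stood at 0.58 against 30.7, ALAS2, the erythroid haem synthesis enzyme, at 0.03 against 10.2, and SLC4A1, the red cell anion exchanger, at 0.01 against 9.82. The lower values of ALAS2 and SLC4A1 rest on about 1 read each, and the ratio of ALAS2 was 340 (63.3 to 14042). HBG1 and HBA2, which have near-identical copies and are uncertain singly, were listed at 0 against 15.6 and 10.9. Markers of other cell types were scarce: 1 megakaryocyte marker, NFE2, and 2 lymphocyte markers, NKG7 at 12.4 against 0.40 and CD79A at 2.54 against 0.61, were detected, and 0 of 15 non-haematopoietic markers.

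Immune and inflammatory lists lay within the range of matched random lists. Cytokines and chemokines, at percentile 52.9 and above the range, at 98.3, at an RPKM of at least 5, split between CXCL8 at 6.87 against 135 and TNF at 0.04 (about 1 read) against 8.75 on one side, and CCL2 at 11.6 against 0.88 and TNFSF13B at 102 against 19.1 on the other. Among 19 detected interferon-stimulated genes 7 were at least 2-fold higher in the library labelled HL-60 relative to the shift and 2 lower; IFITM2 stood at 23.3 against 0.45 and MX2 at 12.4 against 0.29. That list lay at percentile 91.3, and above the range, at 99.87 without a filter on low values and at 99.98 at an RPKM of at least 5. Toll-like receptors and inflammasome genes lay at percentile 15.3, with TLR2 at 2.53 against 7.45. MHC class I genes lay at percentile 27.4, with B2M at 473 against 356, and MHC class II genes at 53.6, with CD74 at 12.1 against 19.6 and HLA-DRA at 0.83 against 1.57, both of which change sides under division by the sum. Only 5 of 14 class II genes found were detected. CD74 and HLA-DRA were the 2 below the shift, and the 3 above it included the regulators RFXANK, at 20.15 against 10.23, and RFXAP, at 2.67 against 1.12. The NADPH oxidase complex lay at percentile 28.2 and integrins and adhesion receptors at 76.6.

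Of the growth and metabolic lists, 3 lay above the range, towards the library labelled HL-60. Of 32 G2/M genes, 28 lay above the shift, with a list percentile of 99.7; CCNB1, the mitotic cyclin, was 5.38-fold higher (4.87 to 5.96) and CENPA 4.60-fold higher (3.78 to 5.63). Of 22 cholesterol synthesis genes, 20 lay above the shift at a percentile of 99.98; INSIG1 was 4.20-fold higher (3.89 to 4.54) and FDFT1, squalene synthase, stood at 194 against 57.6. Replication-dependent histones, at percentile 99.8, lay within the range, at 77.8, once at least 20 reads were required, which kept 18 of 31 members. Genes with no matched length have no read number and drop out there whatever their level. Among them were HIST1H3B, at 522 against 333, and HIST1H3F, at 219 against 29.7. That setting therefore cannot show whether the histone result rests on genes with few reads. With 30 members at an RPKM of at least 5 the list lay above the range, at 100. G1/S and DNA replication genes lay at percentile 52.1, respiratory chain subunits at 91.4, heat shock proteins and chaperones at 95.6, lysosomal hydrolases and cathepsins at 92.7, glycolysis at 40.6 and apoptosis regulators at 23.7. Heat shock proteins lay just above the range under division by the sum (97.64), a pseudocount of 5 (97.52) and no filter (97.88), and lysosomal hydrolases with no filter (97.53). Within these, HSP90AB1 stood at 369 against 97.49, CTSH at 18.8 against 0.84 and PMAIP1, a BH3-only protein, at 6.32 against 18.3. Of reference genes, GAPDH, which changes sides under division by the sum, stood at 164 and 174, and ACTB at 127 and 78.0.

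**Figure D3:**
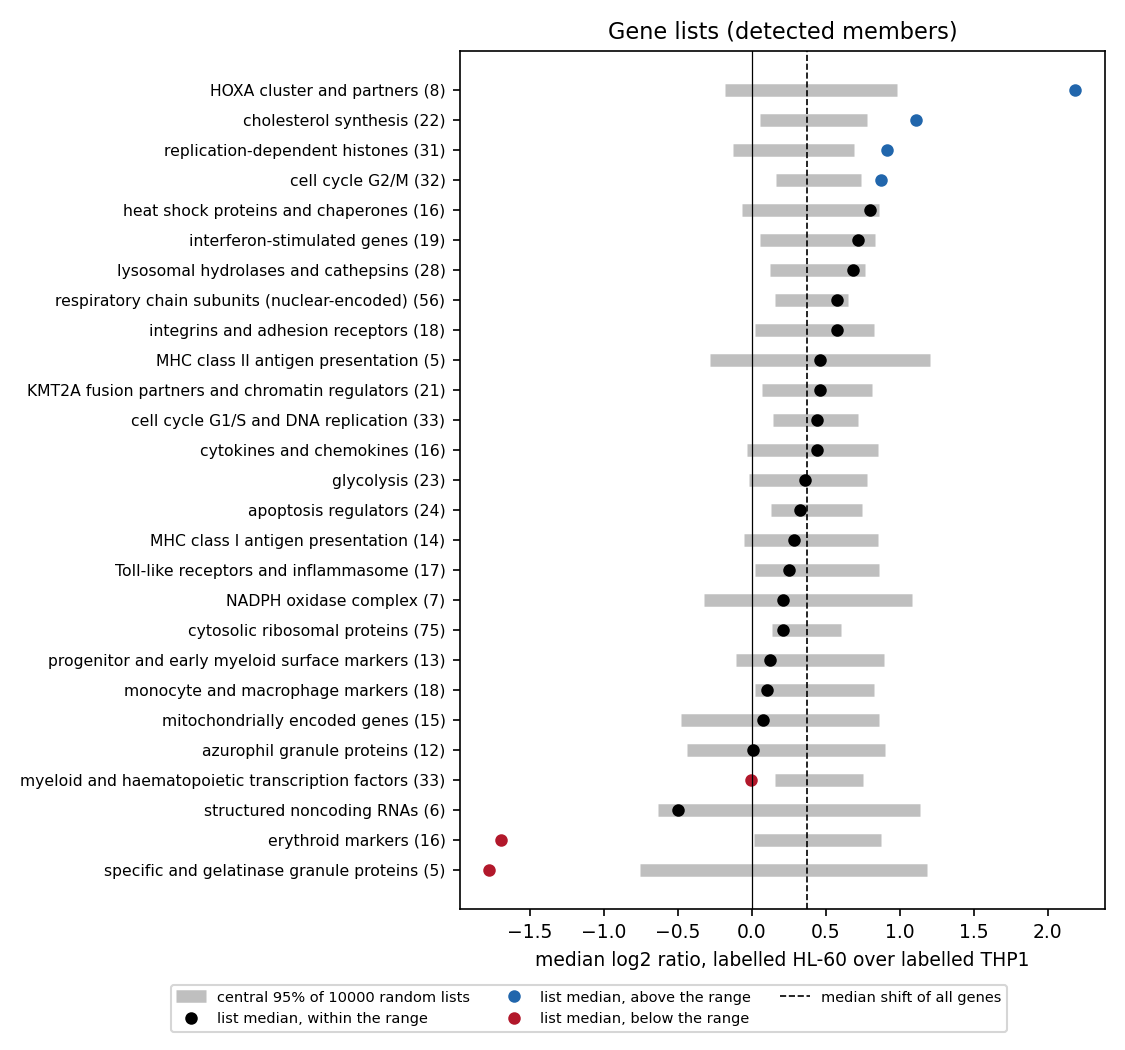
Median log2 ratio, labelled HL-60 over labelled THP1, of the lists with at least 5 detected members (points), 1 of which is not shown, with the central 95% of 10000 random lists matched on expression (grey bars) and the median shift of 0.37 (dashed line). Counts in brackets are detected members; 4 lists lie above their range and 3 below.

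Of 28 lists with at least 5 detected members, 4 lay above and 3 below the matched random range. About 1.4 would lie outside it if their genes were drawn singly at random. Genes of a list can vary together and some lists share genes, so setting these counts side by side is not a test. Random lists matched in addition on whether a row carries a gene symbol, a choice made after the data were seen, put 6 lists below the range, adding azurophil granule proteins at 0.72, monocyte and macrophage markers at 1.99 and cytosolic ribosomal proteins at 0. At an RPKM of at least 5 the HOXA and specific granule lists had too few members for a percentile. The specific granule list also had too few at 20 or more approximate reads, where HP dropped out because it has no length. Centring on the shift turned the sign of 10 list medians between 0 and 0.37, and division by the sum that of myeloid transcription factors and structured noncoding RNAs.

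The last comparison was of RNA classes. Small nucleolar RNAs took 4.29% of approximate mapped reads in the library labelled HL-60 and 11.1% in the library labelled THP1, and protein-coding genes 54.8% and 40.7%. These shares leave out 7293 genes with no entry in GENCODE 29 and so no length, which held 24.1% and 32.4% of summed RPKM. SNORD34 stood at 19292 against 88232 and SNORD58C at 6758 against 49752, while MT-RNR2, the larger mitochondrial ribosomal RNA, stood at 64057 against 48466. Structured noncoding RNAs lay at percentile 3.78, and below the range with no filter (0.19) and with unmatched random lists (0.94), with GAS5, which hosts snoRNAs in its introns, at 1085 against 2538. Only 6 of the 22 names in that list were detected. They included the snoRNA hosts GAS5, SNHG5 and SNHG7 and the snoRNA SNORD13, so the list is not separate from the snoRNA difference. Cytosolic ribosomal proteins lay at percentile 7.62, and below the range with no filter (1.56) and with unmatched lists (1.28), and mitochondrially encoded genes at 26.6. The ribosomal list shares members with the snoRNA hosts, among them its highest, RPL32, at 356 against 979. In the other direction RPL10A stood at 167 against 58.1. How reads with several matches were counted is not given, so the percentile may not reflect ribosomal protein mRNA.

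**Figure D4:**
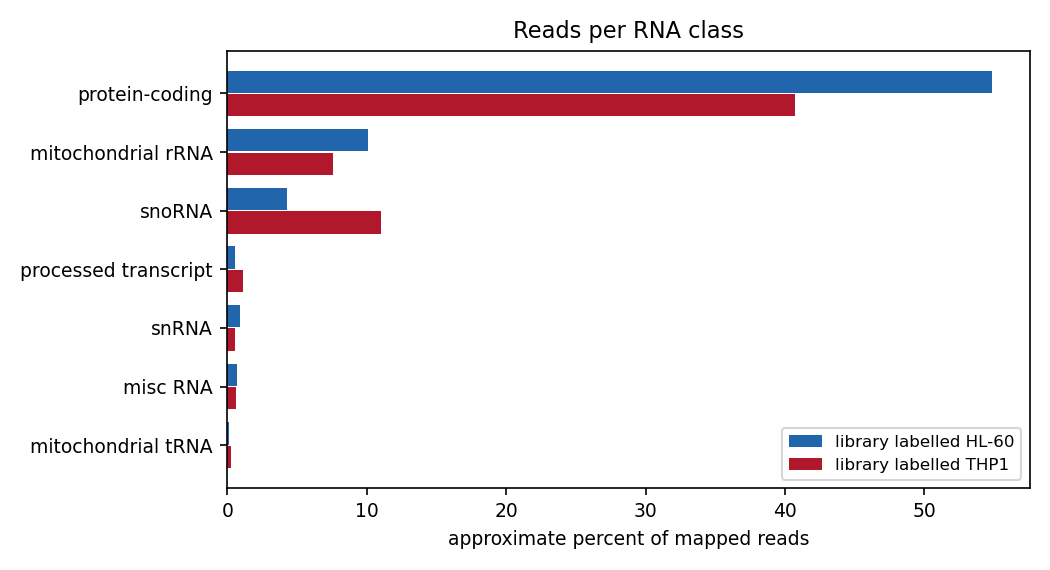
Approximate percent of mapped reads per RNA class, from RPKM, merged exon length and the recovered depth, without the 7293 genes that have no length, in the library labelled HL-60 and the library labelled THP1. Protein-coding genes take 54.8% against 40.7% and snoRNAs 4.29% against 11.1%.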

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

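Restriction to genes with a symbol, the counting interval, leaving out genes listed at 0 and matching of random lists on symbols were chosen after the data were seen; the other alternatives were fixed before. The count of genes at least 4-fold higher in the library labelled HL-60, 312, became 1391 with values divided by their sum, 1037 without the 50 highest rows, 160 centred on the median and 159 on the trimmed mean, 1278, 640 and 73 with pseudocounts of 0.1, 0.5 and 5, and 57 at 8-fold. The count for the library labelled THP1, 272, became 74 and 163 under the same divisions, 646, 423 and 122 with those pseudocounts, 85 at 8-fold, 164 at 20 reads or more and 76 among genes with a symbol. Lists above the random range, 4, became 7 with no filter, 3 at 20 reads or more, and 5 under division by the sum, a pseudocount of 5 and an RPKM of at least 5. Lists below it, 3, became 7 with no filter, 1 at an RPKM of at least 5, 2 at 20 reads or more and without genes listed at 0, 5 with unmatched lists and 6 with lists matched on symbols. Spearman's rho of 0.80 became 0.84 with no filter, 0.71 at an RPKM of at least 5, 0.82 at 20 reads or more and 0.82 among genes with a symbol. The higher thresholds and stricter filters count fewer genes by construction, and the filter of 20 reads or more also leaves out genes with no length. The cause of the other changes was not tested. Summing the rows of a symbol changed no value. Of list medians under alternatives, 396 kept their place against the random range, 24 changed it or left or joined the lists with at least 5 members, and 0 went from above to below or back. These numbers leave out non-haematopoietic markers, which had 0 detected members in the main comparison but count among the 7 lists below the range with no filter. Centring on the median or on the trimmed mean moves a list and its random lists alike. Those settings could not change a place, so the 396 is in part fixed in advance and does not measure robustness. At an RPKM of at least 5 the specific granule and HOXA lists had too few members. No paired analysis was possible because each line has 1 library.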

Other observations

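The second lists of genes linked to KMT2A-rearranged leukaemia, of erythroid genes and of snoRNA hosts were written before their values were seen; the tests of read composition, of HBB against AHSP, of monocyte markers, of hosts outside the fixed lists and of short RNAs, and the scan along chromosomes, were chosen after the result was seen. Coding genes that differed in 1 direction lay in blocks along several autosomes. Medians were taken in windows of 20 neighbouring detected coding genes. In 5 blocks a window median lay above the highest value of 100 shuffles of the gene order, 0.94, and 0 blocks had one below the lowest, -0.83. Windows of 10 genes had been looked at first, and the scan was prompted by neighbouring genes among the largest ratios. The most extreme was on chromosome 6 between 34246380 and 56954628 (GRCh38), with a window median of 1.63 relative to the shift, where 103 of 105 genes, or 98.1%, lay towards the library labelled HL-60. The block was marked out by these same ratios, so a high share follows in part from the choice. In it GLO1, the glyoxalase of methylglyoxal, stood at 225 against 23.9, FANCE at 34.8 against 2.90, FKBP5 at 26.8 against 2.68 and CCND3, cyclin D3, at 58.0 against 8.93. The other blocks were on chromosome 15, at 58.9 to 65.0 Mb and 75.4 to 83.2 Mb, and on chromosome 2, at 170.9 to 177.4 Mb and 181.5 to 195.7 Mb. Among genes named above, HSP90AB1 lies in the chromosome 6 block, CTSH in the block at 75.4 to 83.2 Mb and PDK1 in that at 170.9 to 177.4 Mb. Over its whole length the block at 170.9 to 177.4 Mb had a median of 0.78, under the highest value of the shuffles. Over whole chromosomes the largest displacement among autosomes was the other way, with the 133 coding genes of chromosome 18 at a median of -0.54 relative to the shift. Chromosomes 15, 6 and 8 were displaced nearly as far towards the library labelled HL-60, at 0.51, 0.49 and 0.41. DNA copy number was not measured here.

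Levels of MPO, MYC, MEIS1 and HOXA9 ran against the names of the libraries, since MPO and MYC amplification belong to HL-60 and HOXA9 with MEIS1 to KMT2A-rearranged lines such as THP1. Exchanged labels may account for this: the second KMT2A list lay at percentile 99.5, past the upper bound set before, with 8 of 15 members detected and 4 at least 2-fold above the shift, among them LGALS1 at 201 against 30.8 and CDK6 at 70.7 against 19.5, while CPEB2 stood at 0.80 against 1.77 and JMJD1C at 4.26 against 4.64. Other values lean the other way, as an exchange would put monocyte markers higher in the library labelled HL-60. These markers lay at percentile 6.14, within the range, or at 1.99 with random lists also matched on symbols. S100A8 and S100A9 were higher in the library labelled THP1, though 8 of 18 markers lay above the shift, MNDA among them. Granule genes were no part of that test. Specific and gelatinase granule genes lay at percentile 0.23, with all 5 detected members lower in the library labelled HL-60, 3 of them listed at 0 there. Azurophil granule genes lay at 17.7, with 4 of 12 at least 2-fold higher in each library relative to the shift. A difference between sub-lines was not tested, and the hypothesis of exchanged labels stays open.

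The median coding gene stood lower in the library labelled THP1, which also had more snoRNA reads. The log2 ratio of the coding read shares and the median coding log2 ratio differed by -0.018, but both come from the same values, so the test is void and the part of read composition in the shift stays open. Whether snoRNA reads were counted on exons of their hosts cannot be told apart from other causes: the host list lay at percentile 3.26, short of the bound of 2.5, although at 0.05 with random lists also matched on symbols, and the hosts outside the fixed lists lay at 15. A list median cannot show single cases, and hosts differed. The row with the symbol RPL17, which spans SNORD58C, stood at 434 against 3486. RPL13A, which spans SNORD34, stood at 48.4 against 63.4. Better retention of RNAs under 100 nt also stays open, since non-snoRNA genes of that size had a relative median of -1.71 and those of 100 to 200 nt one of 0.44, but miscellaneous RNAs under 100 nt lay at -0.06 and snoRNAs of 100 to 200 nt at -0.90, so size alone does not order the classes. Library preparation and cell line are the same split here.

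Erythroid genes in the library labelled THP1 could reflect a wider erythroid programme, or RNA carried over from other cells. Of 18 detected members of a second erythroid list, 27.8% lay at least 1 log2 unit below the shift, between the bounds set before. Among all genes with a symbol that share was 5.77%. The list median lay at percentile 0.57, with CA2 at 0.04 against 5.27 and RHAG at 0.03 against 3.07, each about 1 read in the library labelled HL-60. In the other direction XK stood at 5.10 against 0.81, FECH at 5.71 against 3.15 and CPOX at 10.4 against 6.21. Carry-over was to be judged by HBB against AHSP, and the ratio was 0.0854, but the row with the symbol HBB carries the identifier of HBD, a minor globin, so the test is void. HBG1 and HBG2, at 15.6 and 11.4, leave RNA from cells with fetal globin open, and both explanations cannot be told apart here.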
